A study of Mus musculus with 8 samples.

How the data were processed

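Liver RNA came from 8 male mice aged 23 weeks, 4 with a Gpx3 transgene and 4 wildtype of B6/DBA background, per the labels. The mice ate chow with 4% fat to the age of 11 weeks and with 6% fat thereafter. RNA was extracted with Trizol and a silica column, and 100 ng of total RNA was amplified and biotinylated for a 1-colour Illumina bead array. The submitters' processing notes name BeadStudio 1.5.1.3. Values deposited by the authors are an intensity per probe on a linear scale, already background-subtracted, with 33.1% to 35.3% of each array's values below 0. How background was subtracted, and whether arrays were scaled to each other, is not given in the sources used here. A second deposited table holds signals that are not normalized, per the file headers, with detection scores. Its 64 value columns are named in a way that no label gives, so they could not be tied to animals and were not used.

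Groups were taken from the strain in the labels. Animals are numbered within a group in order of deposition, which pairs no animals across groups. Sample titles share one stem in transgenic animals 1 to 3, another in transgenic animal 4 and one more in all wildtype animals; what the stems mean is not stated. The p-values measure only the spread between these animals.

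The test, the 39 gene lists, the rule for named genes and most alternatives were set before the data were examined. The plan put the table with detection scores first, with normexp correction and a detection filter. Because that table could not be used, the planned branch for an already processed table was followed: values below 16 were set to 16, log2 was taken, and no further normalization was applied. Whether the values were in fact normalized between arrays is not known. Probes whose mean log2 signal lay above the lower quartile, which equalled the floor of 4 on the log2 scale, were kept. This left 14759 of 24048 probes, 5646 of them named, for 5026 genes. A log2 fold change near the floor depends on the floor and understates a difference from an unmeasured signal.

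Probe identifiers carry a number that was read as an NCBI Gene ID and matched to a RefSeq gene table of assembly GRCm38.p6, used for names and gene order only. Of 9523 such numbers 8884 (93.3%) were in the table, against 44.9% to 48.9% when the numbers were shifted by 1 to 3. All 7 liver genes checked stood at or above the 99.7th percentile of signal under their own number. Under shifted numbers 1 to 3 of them were found, with median percentiles of 58.1 to 100, so their brightness separates the numberings little. This check replaced another that was not informative, after that was seen. With 9 probes matched by accession, 8893 probes (7413 genes) had a name and 15155 had none. No probe could be tied to Gpx3, and the planned Gpx3 result is not given. Of 4 Y-linked genes looked at, Eif2s3y read 215 to 361 units in all 8 animals, Kdm5d -3.30 to 40.2, and Uty (-24.3 to 9.10) and Ddx3y (-22.7 to 3.90) lay below the floor in all 8.

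Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, transgenic minus wildtype), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Means and SDs are of the deposited intensities, and folds come from the log2 values. Exact permutation tests used the same log2 values. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists with at least 5 measured members, and again with an estimated correlation and with fry. A gene with several probes was represented by its brightest one in the lists. The other 8 lists had too few measured members. Lists without a call that the report describes were chosen after the data were seen.

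The rule for named genes took the genes past the adjusted threshold and, because none passed, the 12 genes of smallest unadjusted p in each direction, leaving out provisional names. It also took the measured members of smallest p of each list described, 4 for the list that passed and 3 for the others, a number chosen after the data were seen within the limit of 4. Tdo2, Ivd, genes of untested lists and genes that varied most between animals were named after their values were seen.

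The comparison was tested on simulated data with the spread of the real arrays, 14759 probes and 200 changed probes, in 20 runs. It recovered 28.4% of 1.5-fold, 53.4% of 2-fold and 72.5% of 4-fold changes, with a mean of 8 false among 110.7 calls. The list test called the amino acid list in 100% of runs at a log2 shift of 0.4 and in 30% at 0.2, in noise without correlation between genes. Alternatives were other scalings, background correction, filters, variance models and list tests, and leaving out each array. Floors of 8 and 32, a filter above 16 on all 8 arrays and a filter on mean signal over 100 were added after the data were seen.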

Results

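Liver gene expression was measured in 8 male mice aged 23 weeks, 4 carrying a Gpx3 transgene and 4 B6/DBA wildtype controls, with 1 array per animal. Gpx3 encodes a secreted selenium-containing glutathione peroxidase that removes peroxides from extracellular fluid. Each array gave a background-subtracted signal for 24048 probes. Median signal per array lay between 11 and 14.2 intensity units, and between 33.1% and 35.3% of probes per array read below 0. The brightest probe of an array reached 47379 to 59796 units. Pearson correlations of log2 signal across the tested probes ranged from 0.978 to 0.986 between transgenic animals, from 0.976 to 0.986 between wildtype animals, and from 0.970 to 0.986 across the groups. These correlations run across probes, which are not independent replicates. The number of arrays, 4 per group, limits the precision of every comparison.

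The comparison asked how gene expression in the liver differed between animals labelled Gpx3 transgenic and wildtype. Transgenic livers had higher mean signals of amino acid breakdown and urea cycle genes, of Eif4ebp3, an inhibitor of cap-dependent translation, and of Pheta1, an endosomal trafficking protein. They had lower mean signals of Cmip, of Ppm1m, a protein phosphatase, and of Cldn2, a tight junction claudin. Eif4ebp3 averaged 1318 ± 345 units in transgenic and 408 ± 114 units in wildtype livers (SD, n = 4 each), a 3.22-fold difference. Of these, the amino acid list passed camera with a preset correlation between genes (adjusted p = 0.00127), and no single probe passed. The list did not pass with an estimated correlation (adjusted p = 0.278) or in fry (adjusted p = 0.118). None of 14759 probes reached an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.0550. At an unadjusted p under 0.05 there were 1006 probes, 476 higher and 530 lower in transgenic livers. The nominal number is 738, which assumes untied values, while 8890 of the 14759 probes lay above 16 on all 8 arrays. The groups did not overlap at 526 probes (3.56%). Chance gives 2.86% for untied values, and less for probes with most arrays at the floor. No probe could be tied to Gpx3, so the transgene itself does not check the labels.

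The 12 named genes with the smallest p among those higher in transgenic livers did not pass the adjusted threshold, and each had non-overlapping groups. Pheta1 averaged 784 ± 63.7 units against 502 ± 44.8 (SD, n = 4 each), a log2 fold change of 0.65 ± 0.09 (SE) with an adjusted p of 0.295 in limma. Eif4ebp3 had a log2 fold change of 1.69 ± 0.25 (SE) and the same adjusted p. Its lowest transgenic value was 846 units, in animal 4, and the other transgenic animals lay between 1364 and 1674 units. Iah1, an esterase, averaged 808 ± 145 units against 467 ± 49.9 (SD, n = 4 each). A second Iah1 probe had a log2 fold change of -0.06. Ppat, the enzyme that commits phosphoribosyl pyrophosphate to purine synthesis, differed by a log2 fold change of 0.87, Vbp1, a prefoldin subunit, by 0.41, and the Mediator subunit Med24 by 0.48. The splicing factor Rbfox2 differed by 0.58 and the transporter Abca5 by 1.19, with 1 wildtype array of Abca5 at the floor of 16 units. Gpr89, a Golgi anion channel, differed by 0.69 at one probe and by 0.11 at a brighter one. Zfp28 (1.08), Gpatch2l (0.51) and Pdxdc1 (0.66) had 2 wildtype arrays each at the floor, so their log2 fold changes depend on it. After normexp background correction with an offset of 50, dim genes had smaller log2 fold changes, such as 0.29 for Gpr89, 0.35 for Ppat, 0.34 for Abca5 and 0.31 for Zfp28. For each of the 12 genes the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 animals can give.

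The 12 named genes with the smallest p among those lower in transgenic livers did not pass either, and their groups did not overlap. Cmip, an adaptor protein of signalling in T cells, averaged 651 ± 23.0 units against 881 ± 54.9 (SD, n = 4 each), a log2 fold change of -0.44 ± 0.07 (SE) with an adjusted p of 0.334 in limma. Ppm1m averaged 762 ± 125 units against 1220 ± 39, and Inpp5a, which removes a phosphate from inositol trisphosphate, 413 ± 72.6 against 653 ± 55.5 (SD, n = 4 each). Cldn2 averaged 1275 ± 139 units against 1771 ± 129 (SD, n = 4 each). Celsr1, a cadherin of planar cell polarity, had a log2 fold change of -0.76, the brain-type creatine kinase Ckb -0.57, and Ikbkg, the regulatory subunit of the IκB kinase complex, -0.48. The homeobox gene Nkx6-2 had a log2 fold change of -0.83. Ugt1a1, the enzyme that conjugates bilirubin, had a log2 fold change of -1.15, at 26.6 ± 8.60 units in transgenic and 56.8 ± 7.50 units in wildtype livers (SD, n = 4 each). Serpina12, which encodes the adipokine vaspin, had a log2 fold change of -1.14 at a dim probe. A bright Serpina12 probe read 18.4 units in transgenic animal 2 and 3241 to 6952 units in the other 7 animals. Ccdc34 (-0.89) had 2 transgenic arrays at the floor. Ugt1a1 and Mtf1 (-0.96), the zinc-responsive transcription factor of metallothionein genes, had 1 each. A second Mtf1 probe went the other way, at 0.11. After normexp with an offset of 50 the log2 fold change of Ugt1a1 was -0.34, that of Nkx6-2 -0.32, that of the dim Serpina12 probe -0.45 and that of Celsr1 -0.39. The exact two-sided permutation p was 0.0286 for each of these genes too.

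**Figure D1:**
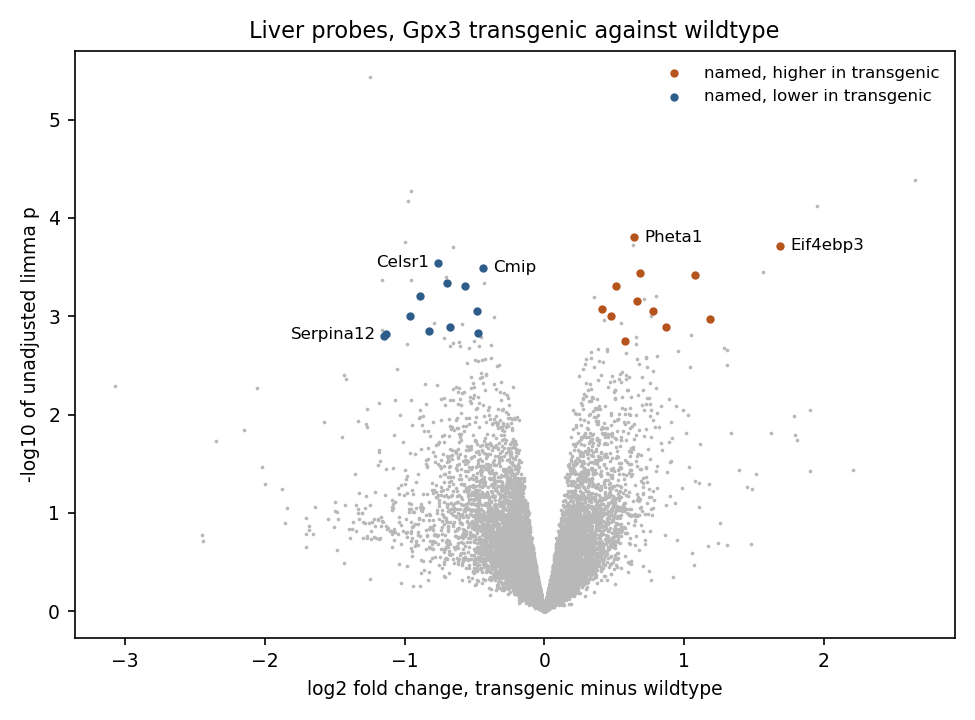
Each point is 1 of 14759 tested probes, with the log2 fold change (transgenic minus wildtype) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Orange and blue points are the 12 named genes of smallest p in each direction, and no probe reached an adjusted p under 0.05.

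**Figure D2:**
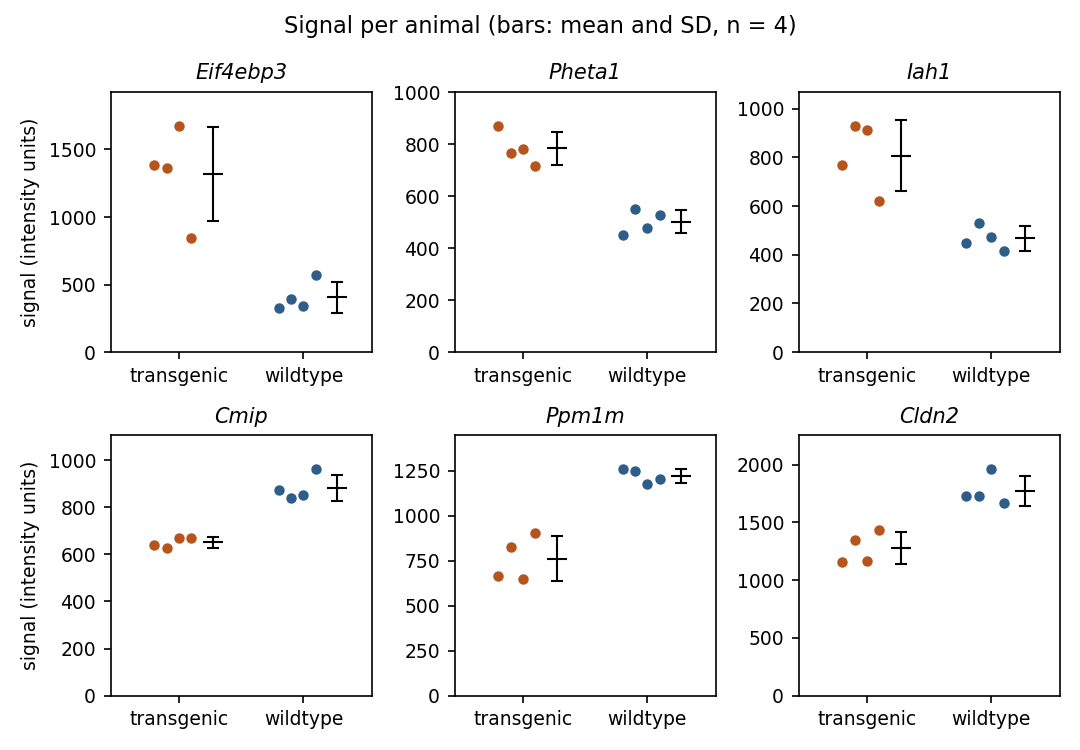
Signal in intensity units of 6 of the named genes in each of the 4 transgenic (orange) and 4 wildtype (blue) animals, with the mean and SD of each group in black. Eif4ebp3, Pheta1 and Iah1 were higher in each transgenic animal than in any wildtype animal, and Cmip, Ppm1m and Cldn2 were lower, although none of the 6 passed the adjusted threshold.

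Among probes that carried no gene name, the smallest p among those higher belonged to scl46162.12.1_3-S, at 128 ± 66.1 units against 15.9 ± 8.00, and to scl50117.17_16-S, at 593.3 ± 208 units against 147 ± 21.6 (SD, n = 4 each). The smallest p among those lower belonged to scl0003765.1_1-S, with a log2 fold change of -1.25 and an adjusted p of 0.0550 in limma, and to scl000977.1_25-S, with -0.95. The 3 probes scl46162.12.1_3-S, scl50117.17_16-S and scl0003765.1_1-S passed under some of the other settings tried, and scl0003765.1_1-S had 2 transgenic arrays at the floor.

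For amino acid catabolism and the urea cycle, all 6 measured members, of 31 on the list, had positive log2 fold changes, with a median of 0.44 and quartiles of 0.36 and 0.48. The list passed camera with a preset correlation between genes (adjusted p = 0.00127 over 31 lists). It did not pass camera with an estimated correlation (adjusted p = 0.278), although that correlation, 0.045 against the preset 0.01, was small. Nor did it pass in fry, which tests whether the genes move one way on balance (adjusted p = 0.118). Ass1, which joins citrulline and aspartate in the urea cycle, averaged 20561 ± 3307 units against 16123 ± 1236 (SD, n = 4 each), and Bhmt, which remethylates homocysteine with betaine, 621 ± 69.2 against 465 ± 104. Prodh, the first enzyme of proline breakdown, averaged 1855 ± 379 units against 1361 ± 230, and Otc, the urea cycle enzyme that makes citrulline, 28.2 ± 5.0 against 16.8 ± 8.60 (SD, n = 4 each). The Otc probe lay close to the floor, and after normexp with an offset of 50 its log2 fold change fell from 0.50 to 0.16. The list median was then 0.35, with all 6 genes still higher. Tdo2, which opens the indole ring of tryptophan, had a log2 fold change of 0.50, and Ivd, an enzyme of leucine breakdown, 0.06. Of the 6 genes 3 had an unadjusted p under 0.05, and 0 passed either over all probes or adjusted over the list alone. Beside this list, endothelial (-0.24), stellate cell (-0.10) and lymphocyte (-0.15) lists had negative medians and neutrophil markers (0.11) a positive one, and none of these passed. With the preset correlation the amino acid list passed in all 8 fits that left out 1 array, with adjusted p between 0.000722 and 0.0209.

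**Figure D3:**
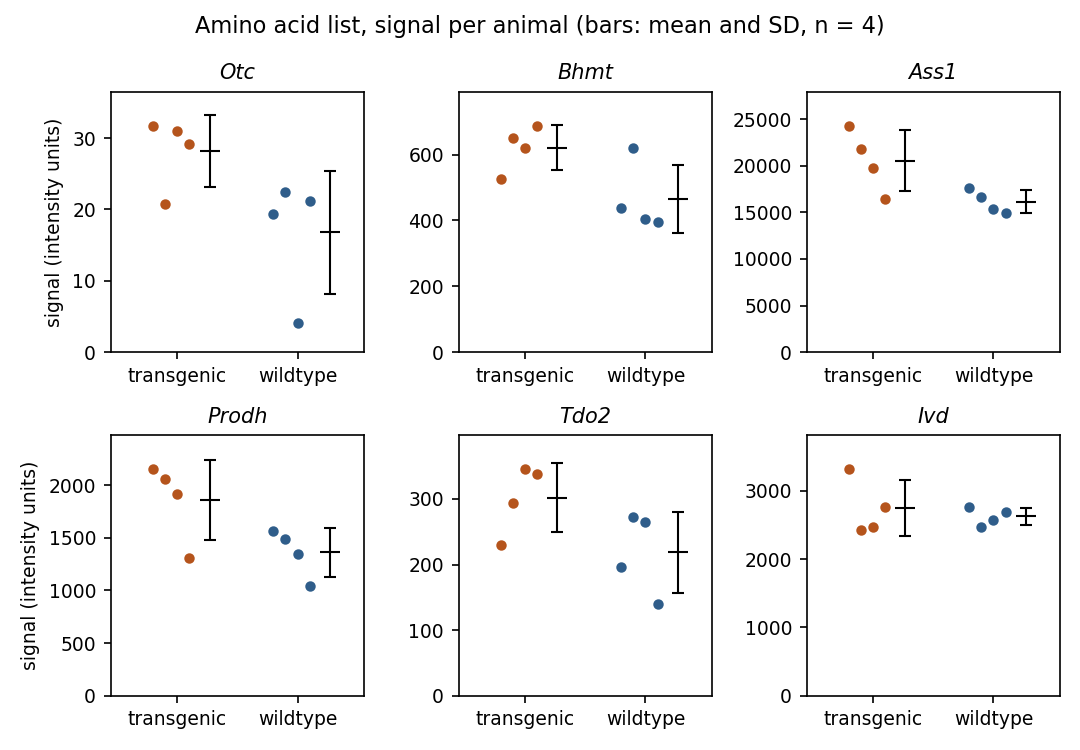
Signal in intensity units of the 6 measured genes of amino acid catabolism and the urea cycle in each of the 4 transgenic (orange) and 4 wildtype (blue) animals, with the mean and SD of each group in black. Group means were higher in transgenic livers for each gene, and the groups overlapped for each gene.

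None of the other 30 lists tested passed. Cell cycle genes came next, with 8 of 11 measured members higher and a median log2 fold change of 0.29 (camera adjusted p = 0.183; 0.839 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, had a log2 fold change of 0.99 at 43.3 ± 14.5 units against 20.9 ± 5.20, and Cdc20, an activator of the anaphase-promoting complex, 0.61 (SD, n = 4 each). Ccnd1, which drives entry into the cycle, averaged 796 ± 142 units against 582 ± 111 (SD, n = 4 each), and its other probes had log2 fold changes of 0.91 and 0.55. The other Cdc20 probe went the opposite way, at -0.23. The cell cycle median dropped to 0.08 after normexp background correction with an offset of 50. Without transgenic replicate 2 the list passed, with an adjusted p of 0.0405.

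Genes of central carbon metabolism did not pass as lists. In the tricarboxylic acid cycle 8 of 12 measured genes were higher, with a median of 0.09 (adjusted p = 0.236). The count was 11 of 12 after quantile normalization and after cyclic loess, 12 of 12 with array medians aligned, and 7 of 12, with a median of 0.03, after normexp with an offset of 50. Sdhb, the iron-sulfur subunit of succinate dehydrogenase, averaged 4550 ± 159 units against 4053 ± 252 (SD, n = 4 each), and Mdh2 and Pdhb had log2 fold changes of 0.41 and 0.33. Of 14 glycolysis and gluconeogenesis genes 6 were higher and 8 lower, with a median of -0.04 and a mean of 0.05, and the test gave the upward direction (adjusted p = 0.910). Pck1, which commits carbon to gluconeogenesis, averaged 675 ± 174 units against 421 ± 104 (SD, n = 4 each). Slc37a4, the glucose 6-phosphate transporter, had a log2 fold change of 0.32 and Ldha -0.10. Mitochondrial oxidative phosphorylation had 17 of 28 genes lower and a median of -0.05 (adjusted p = 0.579), with Ndufa4 at -0.20, Cox6b1 at -0.18 and Ndufc1 at -0.16.

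Lipid genes showed no shared direction past the threshold. Fatty acid and triglyceride synthesis had 6 of 9 genes higher and a median of 0.10 (adjusted p = 0.750). Without transgenic replicate 4 its camera adjusted p was 0.0536, short of the threshold. Relative to each gene's wildtype mean, the list median was -0.21 in that animal. It was 0.25 to 0.36 in the other transgenic and -0.23 to 0.37 in wildtype animals. Acss2, which activates acetate, averaged 2610 ± 683 units against 1809 ± 202 (SD, n = 4 each), Fads2, a fatty acid desaturase, had a log2 fold change of 0.20, and Gpam lay at the floor in 7 of 8 arrays. Fatty acid oxidation had 6 of 10 genes lower and a median of -0.03 (adjusted p = 0.910), with Etfa at -0.07, Acaa1b at -0.12 and Acaa1a at 0.08; a second Etfa probe read 0.13. Cholesterol synthesis had 7 of 12 genes lower and a median of -0.05 (adjusted p = 0.910). Srebf2, the transcription factor of that pathway, had a log2 fold change of 0.24, and Idi1 (-0.38) and Sc5d (-0.24) were at the floor in most arrays. Apolipoprotein and lipoprotein genes had a median of -0.003, which was 0.03 with array medians aligned (adjusted p = 0.910). Within that list, Apoa4, an apolipoprotein of triglyceride-rich particles, averaged 645 ± 178 units against 1174 ± 451, and Apoc2, the cofactor of lipoprotein lipase, 477 ± 97.4 against 642 ± 81.1 (SD, n = 4 each). The lipoprotein receptor Lrp1 had a log2 fold change of 0.37.

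Antioxidant genes, the class to which Gpx3 belongs, did not pass as lists. The glutathione and thioredoxin system had 6 of 11 genes lower and a median of -0.03, which turned to 0.01 after quantile normalization (adjusted p = 0.750). Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, averaged 2274 ± 129 units against 2714 ± 101 (SD, n = 4 each), with non-overlapping groups. Gss, which completes glutathione, had a log2 fold change of -0.28 and Glrx, a glutaredoxin, 0.30. Gclm is also an NRF2 target, and that list had 5 of 8 genes higher, a median of 0.10 and a downward test direction (adjusted p = 0.984). After normexp with an offset of 50 it had 4 of 8 genes higher and a median of 0.04. Srxn1, which reduces overoxidised peroxiredoxins, had a log2 fold change of -0.22, and the conjugating enzyme Gstm3 0.49. Selenoproteins and selenium handling genes had 3 of 5 measured members higher, a median of 0.07, a mean of -0.14 and a downward test direction (adjusted p = 0.910). Scly, which releases selenium from selenocysteine, averaged 1077 ± 49.0 units against 1292 ± 106 (SD, n = 4 each), with non-overlapping groups. Sepsecs, which makes selenocysteinyl tRNA, had a log2 fold change of -0.98 with an SE of 0.63, and Selenof 0.41. With the same normexp correction these were -0.35 and 0.11, and the log2 fold change of Gstm3 was 0.19. A list drawn up as neighbours of Gpx3 had 3 of 6 members higher and a median of -0.02, which was 0.01 after quantile normalization. Its test direction was upward (adjusted p = 0.936). Dctn4 (0.19 and -0.07 at its 2 probes), Tnip1 (0.22) and Cd74 (-0.33) were among its members. Where the members lie in the mouse genome was not checked, so the list does not describe the Gpx3 locus.

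Drug-metabolising and sex-dependent genes were measured as further hepatocyte functions. Cytochrome P450 drug metabolism had 10 of 15 genes lower and a median of -0.12 (camera adjusted p = 0.750). Ugt1a1, with 1 transgenic array at the floor, was the 1 gene that passed when adjusted over the list alone, against 0 over all probes. With the filters on mean signal over 100 and above 16 on all 8 arrays the test direction of this list turned upward. Por, which passes electrons to the P450 enzymes, averaged 1393 ± 326 units against 898 ± 133, and Cyp2c29 539 ± 92.3 against 348 ± 94.9 (SD, n = 4 each). Male-biased liver genes had a median of -0.01, which was 0.02 with array medians aligned (adjusted p = 0.910), with Cyp4a12a at -0.23 and C6 at 0.33. Serpina1e, an α1-antitrypsin gene, had a log2 fold change of -1.71 with an SE of 1.29, since transgenic animal 2 read 409 units and the other 7 animals 20414 to 33464. Female-biased genes had 5 of 8 members lower and a median of -0.24 (adjusted p = 0.910), with Cyp2a4 at -0.29 and Abcd2 at -0.23. Cyp2b9 was at the floor in 3 transgenic and 2 wildtype arrays.

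No list of markers of cells other than hepatocytes passed. Endothelial markers had 5 of 6 genes lower and a median of -0.24 (adjusted p = 0.236; 0.839 with an estimated correlation). Emcn averaged 103 ± 26.3 units against 141 ± 19.5, and Egfl7 140 ± 15.4 against 175 ± 30.7 (SD, n = 4 each), while Pecam1 had a log2 fold change of -1.04 with an SE of 0.57. Stellate cell and fibrosis genes had 5 of 6 members lower and a median of -0.10 (adjusted p = 0.567). Lrat, which stores vitamin A as esters in stellate cells, averaged 277 ± 49.4 units against 378 ± 14.8 (SD, n = 4 each) and passed when adjusted over the list alone. Timp2 had a log2 fold change of -0.39, and Col1a2 lay at the floor in 7 of 8 arrays. Macrophage and Kupffer cell markers had 3 of 5 genes lower and a median of -0.04 (adjusted p = 0.936), with C1qa at -0.29 and with Cd68 and Lyz2 at the floor in 7 of 8 arrays each. Lymphocyte and MHC class II genes had 6 of 7 members lower and a median of -0.15 (adjusted p = 0.750), with Cd74 at -0.33, H2-Ab1 at -0.24 and Cd3e at the floor in 6 of 8 arrays. Neutrophil markers went the other way, with 5 of 7 genes higher and a median of 0.11 (adjusted p = 0.750). After normexp with an offset of 50 the neutrophil median was 0.04 and the stellate cell median -0.05. The log2 fold change of Pecam1 was then -0.38, that of Emcn -0.27 and that of Egfl7 -0.20.

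**Figure D4:**
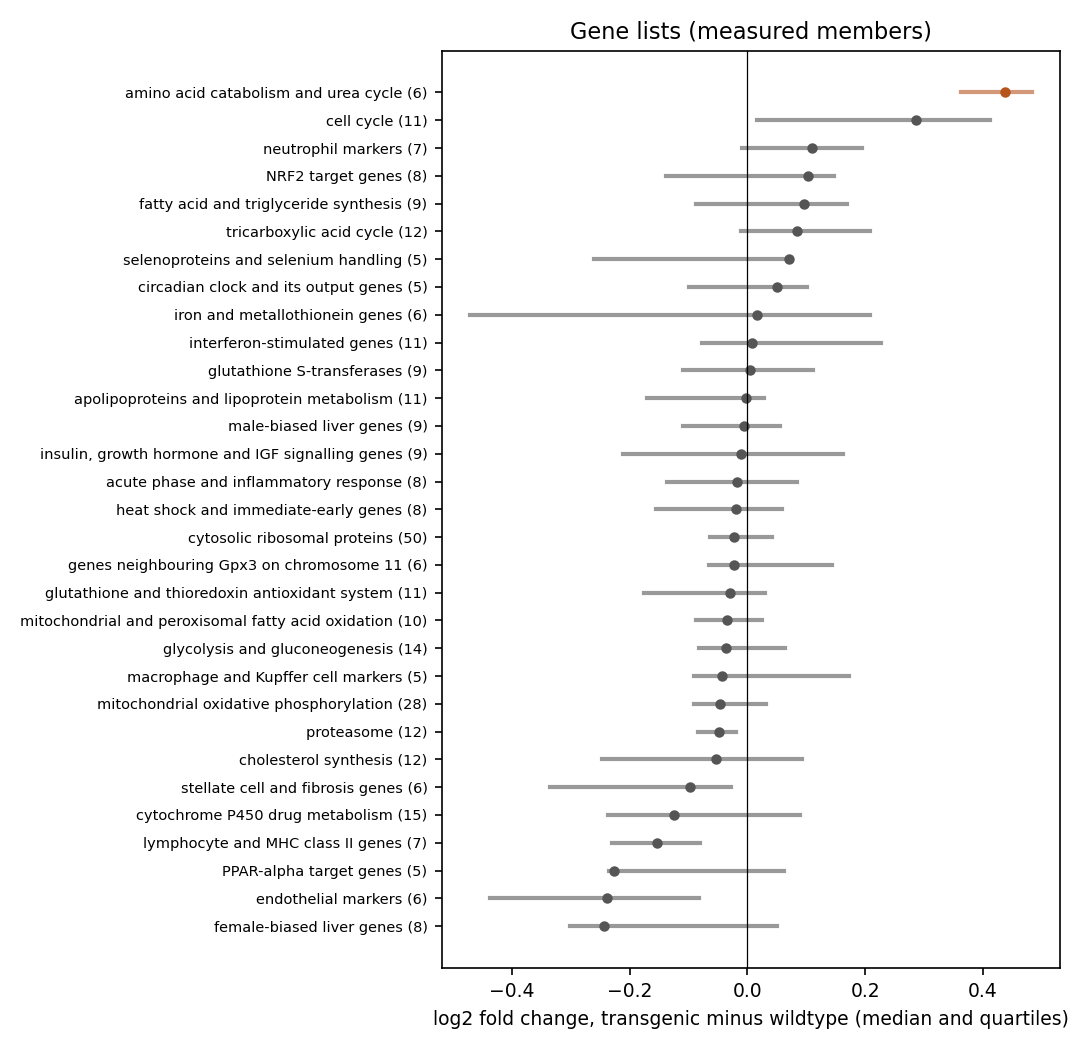
Median log2 fold change (transgenic minus wildtype) of each of the 31 tested gene lists as a point, with a line from the lower to the upper quartile and the number of measured members in brackets. The amino acid list, in orange, passed camera with a preset correlation and did not with an estimated one (adjusted p = 0.278), and the other 30 lists passed neither. The label of the list drawn up as neighbours of Gpx3 names a chromosome that was not checked for its members.

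Animals of one group differed among themselves. On the first principal component, which held 28.1% of the variance, transgenic animals 1 to 3 scored between -25.9 and -16.9 and animal 4 scored 9.50. Wildtype animals 1, 2 and 4 scored between 4.30 and 40.2, and wildtype animal 3 scored -9.60. On the second component, with 15.7% of the variance, transgenic animal 1 scored 28.5 and the other transgenic animals -13.0 to 8.30. Array weights in limma were lowest for transgenic animal 1 (0.537), followed by transgenic animal 4 (0.824). In the amino acid list the median of transgenic animal 4, relative to each gene's mean over the wildtype animals, was 0.33. It was 0.46 to 0.47 in the other transgenic animals and -0.16 to 0.17 in wildtype animals.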

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

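The test of the hepatocyte share was chosen after the result was seen, and the test of the stretch between the serpin genes was chosen after their loss was noticed. An animal is listed here when its gap to the nearest animal of its group of 4, divided by the group's range, was above Dixon's 95% critical value. Chance gives about 1 in 20 such sets, or 10.6 of the 212 checked, and 18 were found. Transgenic animal 2 read low for Gpr89 (64.4 units; others 79.9 to 80.7), Pdxdc1 (22.1), Mtf1 (1.10), Nkx6-2 (31.0) and Cyp4a12a (9241; others 11903 to 12229). The median signal of all probes was also lowest in transgenic animal 2, at 11.0 units against 13.1 to 13.5. Transgenic animal 4 read high for Cyp2a4 (4729 units; others 3543 to 3645), Abcd2 (124), Emcn (142) and Cd3e (26.4), and its amino acid list median of 0.33 was below the 0.46 to 0.47 of the others. Transgenic animal 1 stood apart for Col1a2 (19.5 units) and for the lymphocyte and MHC class II median (-0.56; others -0.08 to -0.05). Wildtype animal 3 read low for Gpatch2l (-7.10 units) and Otc (4.10) and high for Pdhb (406; others 236 to 261). Wildtype animal 2 read high for Ugt1a1 (68.0 units; others 52.1 to 54.3), and wildtype animal 4 had an apolipoprotein median of -0.06 against 0.02 to 0.03.

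The 1006 probes at an unadjusted p under 0.05 exceeded the nominal 738. They also exceeded the median of 610.5 in the other splits of the 8 animals into groups of 4. But 3 of the 35 splits gave as many, with 1166 in the highest other split, so chance cannot be excluded. For probes past the adjusted threshold the splits decide nothing, since the real count was 0 and each of the 35 splits gives at least that. The split with 1166 also gave the highest number past that threshold, 16, and set transgenic animals 1 to 3 and wildtype animal 3 against the rest; whether the highest of so many splits exceeds chance was not tested. Neighbouring genes gave no sign of inherited chromosome segments as a general source, since 24 pairs were both at p under 0.05, against a median of 23 and a 95th percentile of 31 in 10000 shuffles of the gene order. Only adjacent named genes entered that test and its power was not measured, so a few segments stay open. Families behind the title stems may contribute: held out in turn, transgenic animal 4 moved with the other transgenic animals on 49.4% of the probes they selected (42.4% to 52.6% over the choices of wildtype animals) and animals 1 to 3 on 55.5% to 61.1% (51.5% to 59.2% for animal 1), and a difference in litter, transgene dose or label in animal 4 would look alike and was not tested. The stems do not mark the division in the split with 1166, since all wildtype animals share a stem. On the first principal component, too, wildtype animal 3 (-9.60) lay on the side of transgenic animals 1 to 3. Transgenic animal 4 (9.50) lay on the side of the other wildtype animals. H2bc9 and Rpl7a signals divided the animals in the same way, and what sets this division was not tested.

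The amino acid list passed camera with a preset correlation, with its smallest p of the 35 splits in the real one, but it was singled out for that p and did not pass with an estimated correlation (adjusted p = 0.278) or in fry (adjusted p = 0.118). At least 1 list passed in 12 of the 35 splits, with 5 in the highest other split, so a chance call of some list is not excluded. A larger share of hepatocytes was argued against as the whole source, because apolipoprotein genes, made mostly by hepatocytes, had a median of -0.003 and an upper quartile of 0.03, below the amino acid list's lower quartile of 0.36. A partial contribution stays open. Endothelial (-0.24), stellate cell (-0.10) and lymphocyte (-0.15) medians and all 4 erythroid genes (Hba-a1 -0.85) were lower, without passing, while the neutrophil median (0.11) was higher. All 4 measured adipocyte genes were higher too, but hepatocytes also express Pnpla2 among them, so these genes do not mark adipocytes alone. An effect of the transgene on hepatic amino acid metabolism may remain as a hypothesis, not tested apart from the stems of the titles, which no wildtype animal shares with a transgenic one.

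Serpina1e and Serpina12, genes of one serpin cluster on chromosome 12, each had a bright probe lost in transgenic animal 2, at 409 units against at least 20414 and at 18.4 units against at least 3241 in the other 7 animals, while a dim Serpina12 probe was not lost (31.2 units against 29.4 to 105). A fault across a whole array was argued against. Of 4607 bright probes 7 were lost in a single animal, with at most 2 of them in 1 array. The 2 in transgenic animal 2 are the serpin probes themselves, so this count cannot exclude a fault of single probes on that array. A missing stretch of chromosome between the 2 genes was argued against, since the 1 bright probe between them, for Serpina11, kept its signal, at 2721 units against 431 to 1976 in the other animals. Other members were not lost, but Serpina1a, Serpina1b, Serpina1d, Serpina3g, Serpina3k (15251 units against 19686 to 22235) and Serpina3m (2875 against 4852 to 8045) read below every other animal in animal 2, while Serpina10, Serpina11 and Serpina3n (12357 against 6683 to 11167) read above. Alleles that differ between B6 and DBA in these genes, or in the sequences under the probes, could give such a loss in 1 animal of a mixed background, and a wider difference in serpin expression in animal 2 stays open too; neither was tested.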

How the results depend on the processing

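Floors of 8 and 32 and the filters above 16 on all 8 arrays and on mean signal over 100 were chosen after the data were seen. The count of probes past the adjusted threshold, 0 in limma with 1006 at an unadjusted p under 0.05, was 1 after quantile normalization, with array medians aligned, with array weights and at the floor of 32. It was 2 after normexp with an offset of 50 and with eBayes trend and robust, and 0 to 1 leaving out 1 array; cyclic loess, the other filters and the floor of 8 kept 0. The probes that passed differed between settings, and Eif4ebp3 was among them after normexp (adjusted p = 0.0433). The unadjusted count ran from 878 to 1364 leaving out 1 array, and was 663 of 5968 probes with mean signal over 100, where fewer probes were tested and chance gives 298. With no filter it was 1012 of 24048. The probes added there lay at the floor in all 8 arrays and cannot reach such a p, so the nominal 1202 is not what chance gives. Of the probes at an unadjusted p under 0.05, 47.3% were higher. This share was 61.1% after quantile normalization, 59.1% after cyclic loess, 59.7% with array medians aligned and 34.4% without wildtype replicate 3. The balance of directions thus depends on scaling and on 1 animal. The count of lists, 1, was 0 with an estimated correlation and 0 in fry, and 1 to 2 leaving out 1 array; the 2 were reached without transgenic replicate 2, when cell cycle genes passed. The amino acid list passed in 20 of 22 alternatives, with adjusted p from 0.000172 to 0.278 over all of them. Of the 23 lists with a test in all 22 alternatives, 10 kept one test direction throughout; of the 8 others, 4 did where tested. For the 82 named genes, 1491 of 1494 values kept their direction and side of the threshold and 1 passed. Part of this was fixed in advance. The filters and the trend and robust setting use the same log2 values, so they leave a log2 fold change as it was. Genes with non-overlapping groups cannot reverse when 1 array is left out. Sizes changed more: after normexp with an offset of 50, which compresses dim signals, 34 of the 82 log2 fold changes were over 1.5 times smaller, 16 of them with no array at the floor. Cd3e reversed to -0.004 without transgenic replicate 4, in a range up to 0.236 leaving out 1 array, and to -0.019 at the floor of 8, with most arrays at the floor of 16. For 9 genes 13 values could not be had, since all arrays were at the floor. The cause of the other changes was not tested. Not run were the exchange of the 2 tables, detection on all 8 arrays, a slide block and every Gpx3 alternative; trend and robust do not enter camera. No paired analysis was possible because the labels pair no animals. Signals near background limit the dim genes.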

Other observations

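The genes named here were picked after their values were seen, and the list tests were planned. Of the erythroid genes, too few for a list test, all 4 measured members had negative log2 fold changes. Hba-a1, an alpha globin, averaged 9758 ± 534 units in transgenic and 18310 ± 5859 units in wildtype livers, and Hbb-b2, a beta globin, 368 ± 50.8 against 708 ± 301 (SD, n = 4 each). Hbb-b1 had a log2 fold change of -0.62 and Car1, an erythrocyte carbonic anhydrase, -0.70. The adjusted p in limma was 0.592 for Hba-a1 and at least that for the others, and how much blood the samples held is not recorded. All 4 measured adipocyte genes had positive log2 fold changes, with Plin4 at 0.14 and Fabp4 at 0.55. Pnpla2, a triglyceride lipase that hepatocytes also express, averaged 3171 ± 755 units against 2226 ± 180, and Car3 15153 ± 4155 against 11596 ± 787 (SD, n = 4 each), with adjusted p of 0.630 and 0.781 in limma. The bile acid genes Hsd3b7 and Abcc2 had log2 fold changes of -0.21 and -0.23, and Slc10a1, the bile acid uptake carrier, -0.09. Of the 4 measured unfolded protein response genes, Hspa5 (0.22) and Xbp1 (0.06) were higher and Dnajb9 (-0.30) and Sel1l (-0.29) lower.

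Some genes varied far more between animals of one group than the typical probe with a mean signal over 200 units, whose within-group SD was 0.14 on the log2 scale. Mug2, a murinoglobulin, read 185 and 187 units in transgenic animals 2 and 3, 3504 and 5140 in transgenic animals 1 and 4, and 2328 to 2638 in wildtype animals. Cyp4a10, a fatty acid hydroxylase induced by PPAR-alpha, ranged from 232 to 3671 units among transgenic and from 456 to 2053 units among wildtype animals. The histone genes H2bc7, H2bc9 and H2bc15 and the ribosomal protein gene Rpl7a varied together. H2bc9 read 436 to 559 units in transgenic animals 1 to 3 and wildtype animal 3, and 1439 to 4059 units in the other 4 animals. Rpl7a read 360 to 573 and 1195 to 3865 units in the same animals. Prdx2, a peroxiredoxin, read -15.6 units in transgenic animal 3 and at least 168 in the others.

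The lists that the report does not describe did not pass camera. The proteasome had 2 of 12 genes higher, or 5 of 12 after quantile normalization, and a median of -0.05 (adjusted p = 0.750), and PPAR-alpha targets 3 of 5 lower and a median of -0.23 (adjusted p = 0.855). Glutathione S-transferases had a median of 0.004 (adjusted p = 0.910). The medians of interferon-stimulated genes (0.01; adjusted p = 0.750), ribosomal proteins (-0.02; 0.910), circadian genes (0.05; 0.910), acute phase genes (-0.02; 0.910), heat shock genes (-0.02; 0.993), iron genes (0.02; 0.910) and insulin and growth hormone genes (-0.01; 0.936) lay near 0. For ribosomal proteins, acute phase, heat shock, circadian and insulin and growth hormone genes the sign of the median turned under at least 1 scaling, and for acute phase, heat shock and iron genes the median, mean and test differed in sign.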
